A study of Homo sapiens with 18 samples.

How the data were processed

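Gene expression was measured by RNA sequencing. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 RNA-seq kit; whether mRNA was selected and whether the libraries are stranded is not given in the sources used here. The values are raw counts of reads per gene in 2 deposited tables. The submitters' processing notes name fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build hg38, without their role or order. The labels put the knockdown and the overexpression in separate batches, so each comparison stays within a batch and levels are not compared across them. The first table holds the 12 libraries of the knockdown and the second the 6 of the overexpression. All values are whole numbers. Both tables hold the same 58735 genes, and for all 58735 the identifier, chromosome, start, end, strand and merged exon length equal those of GENCODE release 29, from which 45 copies of pseudoautosomal genes on the Y chromosome are left out. No count column was left without a sample (0 unmatched). The replicate numbers are those of the labels.

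Groups follow the labels, with 3 libraries each. Tests ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures in Python 3.11.15 with matplotlib 3.10.9. Each table was fitted on its own with 1 mean per group: genes were kept by filterByExpr, libraries scaled by TMM, and groups compared with edgeR's quasi-likelihood F-test, two-sided. Adjusted p is Benjamini-Hochberg over the genes tested in a comparison, and a gene counts as higher or lower, as having risen or fallen, at an adjusted p under 0.05. The biological coefficient of variation was 0.0864 in the knockdown and 0.0981 in the overexpression. The 3 comparisons were knockdown in A549, knockdown in H358 and overexpression in A549, and a contrast of the 2 knockdowns tested whether they differ between the lines. CPM are counts scaled by library size and TMM factor, with mean ± SD over 3 libraries. RAD21 was also compared with an exact permutation test over all splits of 3 against 3.

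In all, 41 gene lists with 1187 genes, all matched, were fixed in advance. Lists with at least 5 tested members were tested with camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes. The list of MAPK activity is the published score of 10 genes. The groups, the comparisons, the lists, the tests, the rule for naming genes and most alternatives were chosen before the data were examined.

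Genes named are RAD21; the 8 protein-coding genes with the largest rise and the 8 with the largest fall in each comparison, among those with an adjusted p under 0.05, a mean of at least 4 CPM and ranges of the groups that do not overlap, which chance gives for 10% of genes at 3 against 3; in each list described, members that rose and that fell, up to 2 of each, with the smallest adjusted p; members of the MAPK score, of the cohesin list and of the H3K4 lists, called or not; the 5 genes with the largest positive and the 5 with the largest negative difference between the lines; and, among genes called in all 3 comparisons with overexpression opposite to both knockdowns, 6 of each kind by their smallest absolute log2 fold change. A few genes that meet these rules and some of the gene lists, called or not, are not reported here. SPP1, ITGB6, FBXO2, CEACAM6 and LCN2 in the comparison of the lines, the mitochondrial genes and a few members given for context were named after their values were seen.

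Alternatives were DESeq2's size factors, no filter on low counts beyond a total above 0, a filter of at least 10 CPM in 3 libraries, DESeq2's Wald test, limma-voom, the replicate number as a block, only the 6 libraries of a line, all 18 libraries in 1 fit, and each library left out in turn. Chosen after seeing the data were a correction of each library's trends on GC content and then exon length, entered as offsets, robust dispersion estimates, library totals alone for the counts of genes, and leaving out the replicates numbered 3 that stand apart in the comparison of fold changes. Where a group has no counts, a fold is given as a bound against a floor of 3 counts over the group. Intervals of count ratios and the floors cover counting error only. Intervals of correlations and slopes across genes are taken over chromosomes and do not cover the spread between libraries.

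The tests were tried on simulated counts with the means and spread of the data, in which 200 genes were changed. Of genes changed 1.5-fold edgeR recovered 86.6% with the design of the knockdown in A549, 79.1% in H358, 59.7% with the overexpression and 25.4% for the difference between the lines. Of genes changed 2-fold it recovered 100%, 100%, 98.5% and 80.6%. False calls made up 5.91%, 7%, 8.51% and 5.71% of the calls. Of 200 lists without a shift, camera gave 1.5%, 1% and 1% an unadjusted p under 0.05 in the 3 comparisons. The genes were simulated independently of one another, so these shares do not cover lists whose genes move together. A simulated GC trend in 1 group gave 6145 false calls with the A549 knockdown and 5245 with the overexpression. By edgeR after the correction they were 0 and 0. The simulated trend was the same in all libraries of the group and depended only on GC content, which the correction fits. In the data the trends differ between libraries of a group, so these counts do not show how the correction does there. No library was left out of the main tests. Levels of splice forms were not analysed here.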

Results

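RNA from 2 human lung adenocarcinoma cell lines, A549 and H358, was sequenced after the level of RAD21 had been changed. RAD21 is the kleisin subunit that closes the cohesin ring, the complex that holds sister chromatids together and forms chromatin loops. RAD21 was knocked down in both lines with a short hairpin RNA delivered by lentivirus (shRAD21), beside cells given a control vector (shNC). It was also overexpressed in A549 (RAD21OE), beside cells given the empty vector (EV). Each of the 6 groups held 3 libraries, 18 in all. The title of the series concerns H3K4me3, the histone mark of active promoters, and ERK1/2 signalling. Genes of both themes were followed in each comparison beside a broad panel of pathways.

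The 12 libraries of the knockdown held between 15155077 and 19277568 counts each, and the 6 of the overexpression between 13024640 and 14276335. Of the 58735 genes counted, 18939 were tested in the knockdown and 15462 in the overexpression. In 2 groups 1 library stood apart from its replicates. The median absolute log2 difference over genes was 0.28 and 0.27 between replicate 3 and the other shRAD21 libraries of A549, and 0.25 and 0.21 between replicate 3 and the other RAD21OE libraries, against at most 0.11 for any other pair of replicates. The libraries also differed along GC content. Spearman's rho across genes between GC content and the deviation of a library was -0.584, -0.571 and 0.186 in the A549 shRAD21 libraries and 0.0493, 0.222 and 0.626 in the RAD21OE libraries, and it ranged as widely in H358 shNC, at 0.359, 0.206 and -0.485. The log2 fold changes followed GC content too, with rho across genes at -0.414 for knockdown in A549, 0.26 for knockdown in H358, 0.37 for overexpression and 0.47 for the difference between the lines. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Strandedness is not stated either, so counts are less certain where exons overlap a gene on the other strand, as for 40.48% of the exon sequence of DUSP6, 16.51% of PHLDA1, 26.47% of IER3, 30.79% of IER2, 25.64% of SMC4, 16.31% of KRT18, 21.21% of STAG1 and 21.19% of ATF5. Overlaps on the same strand make up 16.23% for CEACAM5, 20.61% for ITGB6 and 13.9% for OSGIN1.

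RAD21 (ENSG00000164754), on the minus strand of chromosome 8 from 116845935 to 116874866 in hg38, followed the labels in every library. In A549 its level was 256.9, 252.9 and 254.6 CPM in the shNC libraries and 128.9, 131.8 and 101.1 CPM in the shRAD21 libraries, 47.4% of control (log2 fold change -1.08, SE 0.08, adjusted p = 2.99e-08). In H358 the control level was 568.8, 588.8 and 602.8 CPM and the knockdown left 378.8, 427.0 and 432.6 CPM, 70.4% of control (log2 fold change -0.51, SE 0.08, adjusted p = 0.000671). The depletion was weaker in H358 than in A549 by the test of the difference (0.57 on the log2 scale, SE 0.12, adjusted p = 0.00228). With overexpression RAD21 rose 7.23-fold, from 195.3, 208.6 and 194.4 CPM with EV to 1520, 1501 and 1306 CPM (log2 fold change 2.85, SE 0.08, adjusted p = 2.9e-10). Of RAD21's exon sequence, 14.2% overlaps a gene on the other strand. The counts do not tell transcripts of the construct from those of the endogenous gene. For each pair of groups an exact two-sided permutation test of RAD21 gave p = 0.1, the smallest value that 3 libraries against 3 can give.

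**Figure D1:**
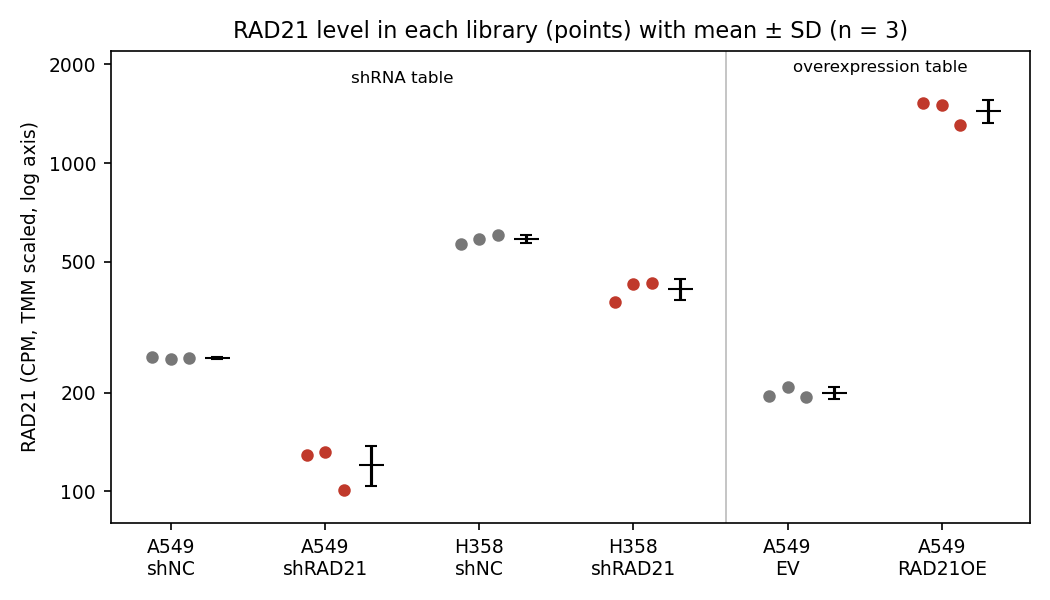
RAD21 level in each library in CPM (TMM-scaled) on a log axis, with points for libraries and bars for the mean ± SD of 3 libraries, for the knockdown and its controls (left) and the overexpression and its control (right). RAD21 averaged 120.6 CPM against 254.8 CPM in A549 and 412.8 CPM against 586.8 CPM in H358 after knockdown, and 1442 CPM against 199.4 CPM with overexpression.

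Knockdown in A549 asked what follows when cohesin is depleted in this line. Most genes of the published score of MAPK activity fell, led by the ETS factors ETV4 and ETV5, although the call of this list was lost with an estimated correlation (adjusted p = 0.076). Immediate early genes of ERK signalling fell less broadly, with a median log2 fold change of -0.08. CEACAM6, an adhesion molecule of the carcinoembryonic antigen family, rose from 10.59 ± 0.627 to 232.3 ± 39.8 CPM (mean ± SD, n = 3), the largest gain in level among the genes with the highest fold changes. Genes of mitosis rose as a group with the preset correlation and not with an estimated one (adjusted p = 0.142). In all, 2721 genes were higher and 2059 lower after knockdown, 25.2% of those tested, and 676 and 491 of them changed at least 2-fold. Without shRAD21 replicate 3 the numbers were 4537 and 3893, and with only the 6 libraries of the line 1649 genes were higher and fewer lower as well. The shRAD21 replicates 1 and 2 had the strongest GC trends of this comparison (rho -0.584 and -0.571). Replicate 3 had 0.186, and the shNC libraries 0.123, 0.114 and -0.207. The larger numbers without replicate 3 are thus not freer of that trend.

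The genes that rose most lay in 2 chromosomal neighbourhoods and a few single loci. On chromosome 19, CEACAM7 (41673307 to 41706976), CEACAM5 (41708585 to 41729798) and CEACAM6 (41750977 to 41772208), cell-surface glycoproteins of epithelia, had log2 fold changes of 4.72 (SE 0.35), 4.74 (SE 0.38) and 4.46 (SE 0.12, adjusted p = 9.96e-14). Their sequences are alike, so reads could be divided wrongly among them. On chromosome 11, the odorant receptor genes OR51E1 (4643420 to 4655488) and OR51E2 (4680171 to 4697854) had log2 fold changes of 5.43 (SE 0.28, adjusted p = 4.73e-09) and 5.12 (SE 0.30, adjusted p = 2.06e-08). LCN2, the siderophore-binding lipocalin of inflamed epithelia, rose from 0.4992 ± 0.265 to 13.17 ± 0.189 CPM (n = 3), and GDA, guanine deaminase, had a log2 fold change of 3.18 (SE 0.22). UGT1A1, the bilirubin glucuronidating enzyme, had 3.25 (SE 0.29), but 49.85% of its exon sequence is shared with other genes of the same strand, so its counts are uncertain. Among the genes that fell most, CACNG7, a regulatory subunit of calcium channels and AMPA receptors, went from 54.78 ± 2.12 to 2.724 ± 0.937 CPM (n = 3, log2 fold change -4.31, SE 0.17, adjusted p = 8.5e-11). EFEMP1, which encodes the matrix protein fibulin-3, and the vesicle release genes UNC13A and SYT1 had log2 fold changes of -3.87 (SE 0.21), -3.56 (SE 0.18) and -2.70 (SE 0.12). IGSF10 (-3.38), the heparan sulfate sulfotransferase HS3ST6 (-2.63), the repressor PRDM1 (-2.60) and the collagen chain gene COL11A1 (-2.54) complete this set. By the rule for naming genes, the 3 shRAD21 libraries lay outside the range of the 3 shNC libraries for every gene. Of the exon sequence of IGSF10, 30.99% overlaps a gene on the other strand.

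Of the 10 genes of a published score of MAPK pathway activity, 9 fell after knockdown in A549 and 1 rose (camera adjusted p = 1.36e-08; adjusted p = 0.076 with an estimated correlation), and the numbers were the same adjusted over the list alone. ETV4, an effector of ERK in transcription, fell from 80.45 ± 4.3 to 20.68 ± 3.06 CPM (n = 3, log2 fold change -1.96, SE 0.10, adjusted p = 1.26e-10) and its relative ETV5 from 54.43 ± 1.77 to 20.46 ± 0.753 CPM (log2 fold change -1.41, SE 0.08). PHLDA1 fell to the same extent (log2 fold change -1.41, SE 0.07). The feedback inhibitors of the pathway fell as well, with log2 fold changes of -1.23 (SE 0.11) for the ERK phosphatase gene DUSP6, -0.97 (SE 0.11) for SPRY4, -0.76 (SE 0.10) for SPRY2 and -0.68 (SE 0.07) for DUSP4. CCND1, cyclin D1, had -0.27 (SE 0.06, adjusted p = 0.00356) and the receptor gene EPHA2 -0.31 (SE 0.10, adjusted p = 0.0373). The call of EPHA2 was lost without any of 5 of the 6 libraries, with an adjusted p of up to 0.182 without shRAD21 replicate 1. EPHA4, another Eph receptor gene, rose at a low level, from 1.013 ± 0.133 to 2.538 ± 0.461 CPM (n = 3, log2 fold change 1.31, SE 0.24). The median log2 fold change of the list was -0.87, -0.91 and -0.79 in the shRAD21 libraries 1, 2 and 3. Of 27 immediate early genes of ERK signalling, 8 fell, among them IER3 (log2 fold change -0.74) and IER2 (-0.89), and 3 rose (camera adjusted p = 0.0433; adjusted p = 0.367 with an estimated correlation; 0.254 after correction for GC content and length). The numbers were 9 and 3 adjusted over the list alone. The call of the list was also lost without shNC replicate 1 (adjusted p = 0.0643) and without shRAD21 replicate 2 (adjusted p = 0.0663).

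Genes of the cell cycle rose more often than they fell. Of 54 genes of the G2 and M phases, 29 rose and none fell (camera adjusted p = 2.65e-06; adjusted p = 0.142 with an estimated correlation), 34 adjusted over the list alone. SMC4, of condensin, had a log2 fold change of 0.68 (SE 0.09), and TOP2A, the topoisomerase of mitotic chromosomes, rose from 787.1 ± 7.11 to 1136 ± 152 CPM (n = 3, log2 fold change 0.53). The median of this list was 0.29, 0.29 and 0.14 in the shRAD21 libraries 1, 2 and 3. Of 42 genes of S phase, 13 rose and 2 fell (camera adjusted p = 0.0078; adjusted p = 0.458 with an estimated correlation; 0.184 after correction for GC content and length), 16 and 2 adjusted over the list alone.

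Epithelial genes rose more often than they fell. Of 32, 14 rose and 4 fell (camera adjusted p = 0.00148; adjusted p = 0.076 with an estimated correlation), 16 and 4 adjusted over the list alone. LSR, of tricellular junctions, rose with a log2 fold change of 2.63 (SE 0.13) and the keratin gene KRT18 with 0.84 (SE 0.05), whereas the tight junction gene CLDN1 fell (-1.78, SE 0.09) and so did JUP, plakoglobin (-1.12, SE 0.06). Of 31 mesenchymal genes, 11 fell and 3 rose (camera adjusted p = 0.0214; adjusted p = 0.134 with an estimated correlation; 0.129 after correction for GC content and length), and the call was lost without shRAD21 replicate 3 (adjusted p = 0.0764). The collagen cross-linking enzyme gene LOXL2 had -1.50 (SE 0.09), while CDH2, N-cadherin, rose (1.03, SE 0.11). Of 24 targets of the coactivator YAP, 13 fell and 4 rose (camera adjusted p = 0.00148; adjusted p = 0.142 with an estimated correlation), among them MYOF (-0.55, SE 0.06) and ANKRD1 (-1.42, SE 0.14). The median of this list was -0.29, -0.32 and -0.06 in the shRAD21 libraries 1, 2 and 3. Of 29 targets of ATF4, the factor of the integrated stress response, 12 fell and 3 rose (camera adjusted p = 0.0022; adjusted p = 0.367 with an estimated correlation). Of 43 interferon-stimulated genes, 14 rose and 3 fell (camera adjusted p = 0.00731; adjusted p = 0.0988 with an estimated correlation). Among them DTX3L rose (0.89, SE 0.08). Of 52 genes of the protocadherin clusters, whose promoters contact enhancers through cohesin, 15 rose and 1 fell (camera adjusted p = 0.00731, and 0.134 with an estimated correlation). Many of the 52 were at low levels in A549, and only 19 passed the filter in the overexpression. Several that rose had few counts with shNC, such as PCDHA2 (0.265 CPM), PCDHB8 (0.202 CPM) and PCDHB14 (0.356 CPM). PCDHA4 (1.06), PCDHGC3 (0.94) and PCDHAC1 (-1.28) share exons with other members of their clusters, so their counts are uncertain. Adjusted over the list alone, the genes higher and lower numbered 3 and 11 for mesenchymal genes, 4 and 15 for YAP targets, 3 and 13 for ATF4 targets, 14 and 4 for interferon-stimulated genes and 15 and 1 for protocadherins.

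Cohesin and the H3K4 methylation machinery moved little as groups, and for the methyltransferase list the median and mean (0.01 and 0.0006) lay above 0 where camera's direction was down. Of 21 cohesin genes, 6 rose and 3 fell in A549, RAD21 included (camera adjusted p = 0.411), 9 and 3 adjusted over the list alone. STAG1 (0.55, SE 0.10) and PDS5B (0.50, SE 0.09), which bind the ring, and the loop anchor gene CTCF (0.30, SE 0.07) rose. The rises of WAPL (0.29), PDS5A (0.23) and PTTG1 (0.21) were each lost under several settings, with adjusted p of up to 0.177, 0.617 and 0.221. REC8, the meiotic kleisin gene, had -0.52 (SE 0.14; adjusted p = 0.0571 after correction for GC content and length), and CDCA5 -0.31 (adjusted p = 0.0116; up to 0.0653 with 1 library left out, shNC replicate 1). The ring partners SMC1A (0.06) and SMC3 (0.13) did not pass the test. Of 21 genes of H3K4 methyltransferase complexes, KMT2C rose (0.55, SE 0.08, adjusted p = 8.99e-05) and BOD1 (-0.57, SE 0.10) and KMT2D (-0.25, SE 0.08) fell (camera adjusted p = 0.862). KMT2D had an adjusted p of up to 0.117 without shRAD21 replicate 1. Of 7 H3K4 demethylase genes, KDM5C (-0.33, SE 0.08) and KDM1B (-0.27) fell and KDM1A (0.21) rose (camera adjusted p = 0.766). The calls of KDM1B and KDM1A were lost under several settings, with adjusted p of up to 0.108 without shNC replicate 1 and 0.145 with no filter on low counts. The numbers of both H3K4 lists were the same adjusted over the list alone.

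**Figure D2:**
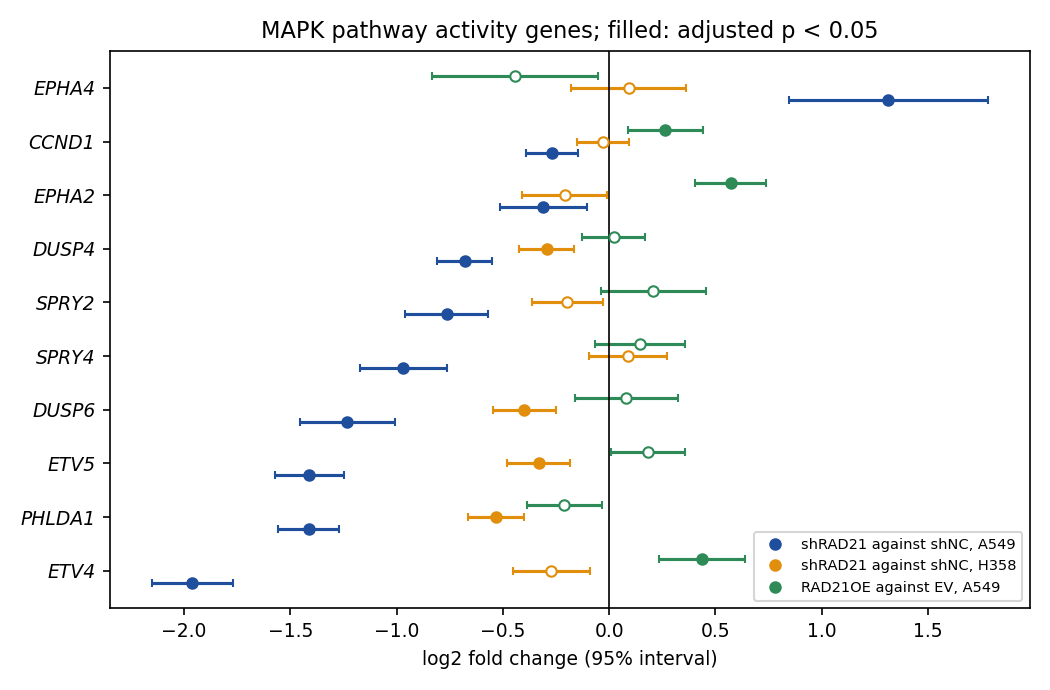
Log2 fold changes with 95% intervals of the 10 genes of the MAPK pathway activity score after knockdown in A549 (blue), knockdown in H358 (orange) and overexpression in A549 (green), filled where the adjusted p is under 0.05. In A549 9 of the genes fell after knockdown, in H358 4 fell, and with overexpression 3 rose.

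Knockdown in H358 asked whether the second line responds alike. Interferon-stimulated genes rose as a group, and growth factor ligands and targets of ATF4 and NRF2 fell. IFI27 rose from 5.47 ± 0.221 to 27.3 ± 8.45 CPM and IFI6 from 21.07 ± 1.24 to 59.28 ± 6.54 CPM (mean ± SD, n = 3). SPP1, the secreted matrix protein osteopontin, fell from 114.4 ± 10.1 to 28.77 ± 2.63 CPM (n = 3, log2 fold change -1.99, SE 0.09, adjusted p = 8.12e-10). In all, 716 genes were higher and 875 lower, 8.4% of those tested, of which 123 and 61 changed at least 2-fold. These numbers depended on single libraries: with 1 library left out in turn, between 347 and 386 genes were higher, and 431, 490 and 496 lower without shNC replicates 1, 2 and 3 and 488, 408 and 419 lower without shRAD21 replicates 1, 2 and 3. They also depended on the model, with 2186 higher and 2287 lower when only the 6 libraries of the line were fitted, 1713 and 1700 after correction for GC content and length, and 455 and 583 with the replicate number as a block.

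The genes that rose most were IFI27 (log2 fold change 2.32, SE 0.20, adjusted p = 1.97e-06), the kinase gene NRK (1.99, SE 0.23), the potassium channel gene KCNH2 (1.75, SE 0.18), OAS2, which senses double-stranded RNA (1.67, SE 0.22), and the retinoid transporter gene ABCA4 (1.64, SE 0.23). They were followed by the matrix gene SPARC (1.56, SE 0.23), IFI6 (1.49, SE 0.17) and FBXO2, which targets glycoproteins for ubiquitination (1.42, SE 0.16). Those that fell most after DHRS9, a retinol dehydrogenase gene (-2.05, SE 0.25), and SPP1 were PKNOX2 (-1.57, SE 0.17), the niacin receptor gene HCAR2 (-1.29), TMC1 (-1.25), of hair cell channels, the glutathione-degrading enzyme gene CHAC1 (-1.22, SE 0.17), LEMD1 (-1.20) and DTX4 (-1.20). For each of these 16 genes the 3 shRAD21 libraries lay outside the range of the 3 shNC libraries, which the rule for naming genes requires.

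Of 43 interferon-stimulated genes in H358, 13 rose and none fell (camera adjusted p = 2.71e-07; adjusted p = 0.0113 with an estimated correlation), 21 adjusted over the list alone. MX1, an antiviral GTPase gene, rose from 10.69 ± 0.492 to 26.4 ± 1.53 CPM (n = 3, log2 fold change 1.30, SE 0.11). Of 29 ATF4 targets, 18 fell and 1 rose (camera adjusted p = 1.62e-16; adjusted p = 0.0269 with an estimated correlation). SLC7A11, the cystine importer gene, fell from 123.3 ± 9.23 to 62.61 ± 2.96 CPM (n = 3, log2 fold change -0.98, SE 0.10) and DDIT4, an inhibitor of mTORC1, by the same log2 fold change (-0.98, SE 0.10), although 41.16% of its exon sequence overlaps a gene on the other strand. The exception was ATF5 (0.59, SE 0.17, adjusted p = 0.032; up to 0.132 with 1 library left out, shNC replicate 1). Of 29 targets of NRF2, the factor of the oxidative stress response, 7 fell and none rose (camera adjusted p = 1.22e-05; adjusted p = 0.0113 with an estimated correlation), 11 adjusted over the list alone, with SLC7A11 and the export pump gene ABCC3 (-0.69, SE 0.07) in front. Of 22 growth factor ligands, 9 fell and none rose (camera adjusted p = 0.000115; adjusted p = 0.0172 with an estimated correlation). AREG, amphiregulin, fell from 292.6 ± 17 to 146.7 ± 3.52 CPM (n = 3, log2 fold change -0.996, SE 0.07, adjusted p = 1.87e-07) and EREG, epiregulin, from 309.5 ± 14 to 192.4 ± 12.6 CPM (log2 fold change -0.69, SE 0.07). Of 28 genes of migration and invasion, 10 fell and 1 rose (camera adjusted p = 7.39e-06; adjusted p = 0.0113 with an estimated correlation), with the integrin genes ITGA6 (-0.53, SE 0.07) and ITGB6 (-0.75, SE 0.10) lower and L1CAM (1.45, SE 0.40, adjusted p = 0.0322; up to 0.121 without shRAD21 replicate 1) higher. Adjusted over the list alone, the genes higher and lower numbered 1 and 19 for ATF4 targets, 1 and 10 for growth factor ligands and 1 and 13 for migration and invasion.

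The MAPK activity score fell less broadly in H358 than in A549. Of the 10 genes, 4 fell and none rose (camera adjusted p = 0.000437; adjusted p = 0.181 with an estimated correlation), 5 adjusted over the list alone. PHLDA1 had a log2 fold change of -0.53 (SE 0.07) and DUSP6 of -0.40 (SE 0.08), while ETV5 (-0.33, SE 0.08, adjusted p = 0.00997) and DUSP4 (-0.29, SE 0.07, adjusted p = 0.00877) each lost the call without any of 4 single libraries, with adjusted p of up to 0.0703 without shNC replicate 2 and 0.058 without shNC replicate 1. ETV4 (-0.27), EPHA2 (-0.21), SPRY2 (-0.20), CCND1 (-0.03), SPRY4 (0.09) and EPHA4 (0.09) did not pass the test. Genes of DNA replication rose more often than they fell. Of 42 genes of S phase, 16 rose and none fell (camera adjusted p = 2.18e-14, and 0.1 with an estimated correlation), 25 adjusted over the list alone. Log2 fold changes were 0.50 (SE 0.07) for the helicase subunit gene MCM6 and 0.44 (SE 0.07) for UNG, which removes uracil from DNA. Of 32 MYC targets, 6 rose and none fell (camera adjusted p = 9.49e-07; adjusted p = 0.185 with an estimated correlation), led by the polyamine synthesis genes ODC1 (0.62, SE 0.07) and SRM (0.44, SE 0.07). Of 54 genes of the G2 and M phases, 2 rose and 1 fell (camera adjusted p = 0.0268; adjusted p = 0.547 with an estimated correlation), a call lost without shNC replicate 1 (adjusted p = 0.149), shRAD21 replicate 2 (0.0544) or shRAD21 replicate 3 (0.11). None of the 52 protocadherin genes passed edgeR's test (2 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma-voom). Among 21 cohesin genes, REC8 (0.70, SE 0.12), STAG1 (0.40, adjusted p = 0.0254) and CDCA5 (0.32, adjusted p = 0.0218) rose and RAD21 fell (camera adjusted p = 0.703). The median of the cohesin list was -0.02 and its mean 0.03, with camera's direction up. STAG1 and CDCA5 lost the call with single libraries left out, with adjusted p of up to 0.139 without shRAD21 replicate 3 and 0.115 without shNC replicate 1. None of the 21 H3K4 methyltransferase genes passed edgeR's test (3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom; camera adjusted p = 0.524). Of the 7 demethylase genes RIOX1 rose (0.64, SE 0.11, adjusted p = 0.00129; camera adjusted p = 0.809). Adjusted over the list alone, 10 MYC targets rose and none fell, and the numbers for the G2 and M phases, protocadherins, cohesin and both H3K4 lists were the same. The median and mean lay on different sides of 0 for demethylases (-0.09 and 0.03) and for protocadherins (0.02 and -0.0001), and camera's direction was down for both.

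The effects of knockdown differed between the lines for many genes. RAD21 was left at 47.36% of control in A549 and 70.35% in H358, so the line and the strength of depletion cannot be told apart. The difference also followed GC content across genes (rho 0.47). The test of the difference called 3325 genes, with 1442 higher and 1883 lower in H358 relative to A549, 17.6% of those tested. Without A549 shRAD21 replicate 3 the numbers were 3507 and 3841, without A549 shNC replicate 1 the first was 932, and without H358 shNC replicate 3 the second was 1246. The fall of the MAPK activity score was larger in A549: 7 of its 10 genes had a difference above 0 and 1, EPHA4, below 0, or 8 and 1 adjusted over the list alone (median difference 0.70 on the log2 scale, camera adjusted p = 1.05e-05; adjusted p = 0.107 with an estimated correlation). For ETV4 the difference was 1.69 (SE 0.13, adjusted p = 1.05e-07) and for ETV5 1.08 (SE 0.11). SPP1 rose in A549 (log2 fold change 1.09) and fell in H358 (-1.99), a difference of -3.09 (SE 0.13, adjusted p = 8.03e-11). The integrin gene ITGB6 also moved in opposite directions (1.75 and -0.75), and FBXO2 fell in A549 (-1.37) and rose in H358 (1.42). CEACAM6 rose more in A549 (difference -3.69, SE 0.25), and LCN2 (-4.84, SE 0.44) rose there and did not pass the test in H358 (-0.16).

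Overexpression of RAD21 in A549 asked for the reverse change. Among the genes that fell most, C3, the central complement component, fell from 94.1 ± 5.31 to 16.46 ± 2.1 CPM and TGM2, the tissue transglutaminase gene, from 613.0 ± 13.3 to 147.3 ± 20 CPM (mean ± SD, n = 3). Targets of MYC and NRF2 rose as groups with the preset correlation and not with an estimated one (adjusted p = 0.281 and 0.266). OSGIN1, an oxidative stress gene, rose from 73.57 ± 9.33 to 292.9 ± 29.3 CPM. The mRNAs encoded in mitochondria fell while both mitochondrial ribosomal RNAs rose. In all, 2177 genes were higher and 2120 lower, 27.8% of those tested, and 161 and 539 of them changed at least 2-fold. Leaving out an EV library lowered both numbers, to 1205 and 1235 without replicate 1, 1112 and 1065 without replicate 2, and 1336 and 1369 without replicate 3.

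Besides RAD21, the genes that rose most were SHISA3 (log2 fold change 3.42, SE 0.27), the endothelial transcription factor gene KLF2 (2.07, SE 0.15), OSGIN1 (1.99, SE 0.11), the keratin gene KRT4 (1.71, SE 0.12), NECAB2, which binds calcium (1.67, SE 0.14), CDRT1 (1.61, SE 0.19) and ANKRD1, a YAP target (1.61, SE 0.11). Of the exon sequence of CDRT1, 31.31% is shared with another gene of the same strand. Those that fell most were C3 (-2.52, SE 0.11, adjusted p = 2.09e-08), the matrix genes SPARC (-2.50, SE 0.19) and SPOCK1 (-2.25, SE 0.18), the collagen-binding integrin gene ITGA11 (-2.20, SE 0.15), TGM2 (-2.06, SE 0.09, adjusted p = 2.76e-08), DOCK2, an activator of Rac (-2.00, SE 0.18), OASL, an interferon-induced gene (-1.87, SE 0.16), and SLITRK6 (-1.84, SE 0.26). The 3 RAD21OE libraries lay outside the range of the 3 EV libraries for each of these genes, which the rule for naming genes requires.

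Of 32 MYC targets, 21 rose and none fell with overexpression (camera adjusted p = 3.85e-10; adjusted p = 0.281 with an estimated correlation), 24 adjusted over the list alone. RRS1 (0.80, SE 0.10) and RRP12 (0.64, SE 0.09), of ribosome assembly, led them. Of 29 NRF2 targets, 18 rose and 1 fell (camera adjusted p = 2.54e-09; adjusted p = 0.266 with an estimated correlation). AKR1B10, an aldo-keto reductase gene, rose from 2837 ± 66.1 to 5921 ± 404 CPM (n = 3, log2 fold change 1.06, SE 0.07), and the median of the list was 0.26, 0.30 and 0.50 in the RAD21OE libraries 1, 2 and 3. Of 24 YAP targets, 12 rose and 2 fell (camera adjusted p = 0.00556; adjusted p = 0.281 with an estimated correlation), with CYR61 at 0.73 (SE 0.10). Of 36 interferon-stimulated genes, 23 fell and 3 rose (camera adjusted p = 1.22e-07; adjusted p = 0.266 with an estimated correlation), 24 and 3 adjusted over the list alone, with SAMD9 (-1.60, SE 0.15) and OASL lower and OAS1 higher (0.52, SE 0.10). Of 29 mesenchymal genes, 15 fell and 2 rose (camera adjusted p = 0.000243; adjusted p = 0.307 with an estimated correlation). The collagen gene COL5A1 had -1.73 (SE 0.10) and TGFBI -1.32 (SE 0.09), and COL3A1 (0.75) and the matrix protease gene MMP14 (0.83) rose. The median of this list was -0.59, -0.39 and -0.22 in the RAD21OE libraries 1, 2 and 3. Of 27 genes of migration and invasion, 13 fell and 2 rose (camera adjusted p = 0.0214; adjusted p = 0.281 with an estimated correlation), among them the laminin gene LAMA3 (-0.84), a call lost without RAD21OE replicate 1 (adjusted p = 0.0529). Adjusted over the list alone, the genes higher and lower numbered 21 and 1 for NRF2 targets, 13 and 3 for YAP targets, 3 and 16 for mesenchymal genes and 5 and 14 for migration and invasion.

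The MAPK activity score did not move as a group with overexpression. Of its 10 genes, 3 rose and none fell (camera adjusted p = 0.179): EPHA2 (0.57, SE 0.09, adjusted p = 0.000459), ETV4 (0.44, SE 0.10, adjusted p = 0.0079; 0.0546 without EV replicate 3) and CCND1 (0.27, adjusted p = 0.0432; up to 0.171, after correction for GC content and length, and lost without any of 5 single libraries). By fry, which asks only whether the list's own genes move one way, the adjusted p was 0.0141. The values of PHLDA1 (-0.21), EPHA4 (-0.44), SPRY2 (0.21), ETV5 (0.18), SPRY4 (0.15), DUSP6 (0.08) and DUSP4 (0.02) did not pass the test. Of 21 H3K4 methyltransferase genes, 8 rose and 1 fell (camera adjusted p = 0.00978; adjusted p = 0.281 with an estimated correlation), 10 and 2 adjusted over the list alone. HCFC1 (0.53, SE 0.08, adjusted p = 0.000744), a shared subunit of these complexes, KMT2B (0.50, SE 0.09), MEN1, menin (0.48, SE 0.10), and SETD1A (0.43, SE 0.09) kept their calls in every setting, and PSIP1, a chromatin tether, fell (-0.52, SE 0.13). CXXC1 (0.36), WDR5 (0.30), SETD1B (0.28) and PAXIP1 (0.28) rose, but each lost the call with single libraries left out, with adjusted p of up to 0.132 without EV replicate 2, 0.11 without EV replicate 1, 0.126 without EV replicate 2 and 0.162 without EV replicate 2. Of 7 demethylase genes KDM1B rose (0.43; adjusted p of up to 0.0831 without EV replicate 1). Of 20 cohesin genes, 5 rose, RAD21 included, and 3 fell (camera adjusted p = 0.199). CTCF (0.54, SE 0.08, adjusted p = 0.000446), CDCA5 (0.47, SE 0.09) and the ring partner SMC1A (0.34, SE 0.07) rose, as did SMC3 (0.28, adjusted p = 0.0449; up to 0.158 without EV replicate 1). ESCO1 (-0.62), REC8 (-0.51) and HDAC8 (-0.44) fell, with adjusted p of up to 0.0875 without EV replicate 3, 0.112 without EV replicate 2 and 0.103 without EV replicate 3. With p adjusted over the list alone, 7 cohesin genes rose and 3 fell, and the numbers for the MAPK score and the demethylases were the same.

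All 13 mRNAs encoded in the mitochondrial genome fell with overexpression and both ribosomal RNAs rose (15 genes, camera adjusted p = 7.98e-10; adjusted p = 0.266 with an estimated correlation), the same numbers as adjusted over the list alone. MT-RNR1, the 12S rRNA, rose from 1009 ± 90.1 to 2663 ± 147 CPM (n = 3, log2 fold change 1.40, SE 0.08) and MT-RNR2, the 16S rRNA, from 14160 ± 725 to 20740 ± 1260 CPM (log2 fold change 0.55, SE 0.07). MT-CO3, a subunit of cytochrome c oxidase, fell from 8037 ± 195 to 2627 ± 107 CPM (n = 3, log2 fold change -1.61, SE 0.07), and the other mRNAs lay between -1.50 for MT-ND6 and -0.37 for MT-ND2. Mitochondrial genes took 7.87%, 8.51% and 8.04% of the counts in the EV libraries and 5.68%, 5.76% and 5.34% in the RAD21OE libraries. After knockdown in A549 that share was 10.3%, 9.75% and 7.45%, against 8.59%, 8.74% and 8.94% with shNC, replicate 3 lying on the other side of the controls from replicates 1 and 2. MT-RNR1 rose after that knockdown too, from 1273 ± 44.3 to 1905 ± 407 CPM (n = 3, log2 fold change 0.58, SE 0.11, adjusted p = 0.000597).

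**Figure D3:**
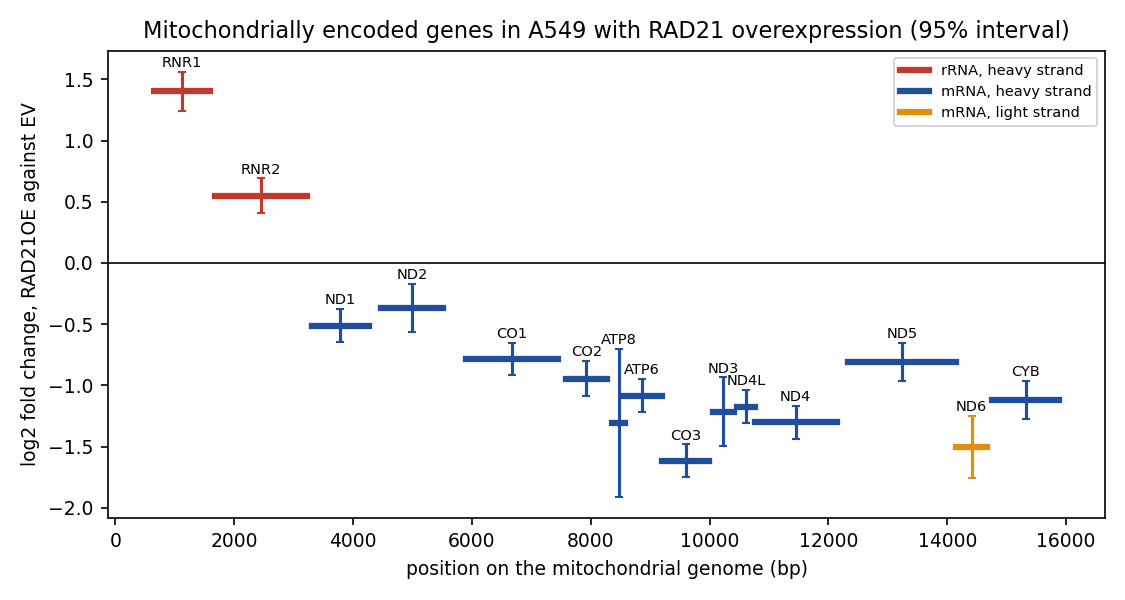
Log2 fold change with 95% interval of each mitochondrial rRNA and mRNA with RAD21 overexpression in A549, drawn as a bar over the gene's position in base pairs on the mitochondrial genome (red, rRNA; blue, mRNA of the heavy strand; orange, mRNA of the light strand). MT-RNR1 and MT-RNR2 lie at 1.40 and 0.55, and all mRNAs lie below 0.

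**Figure D4:**
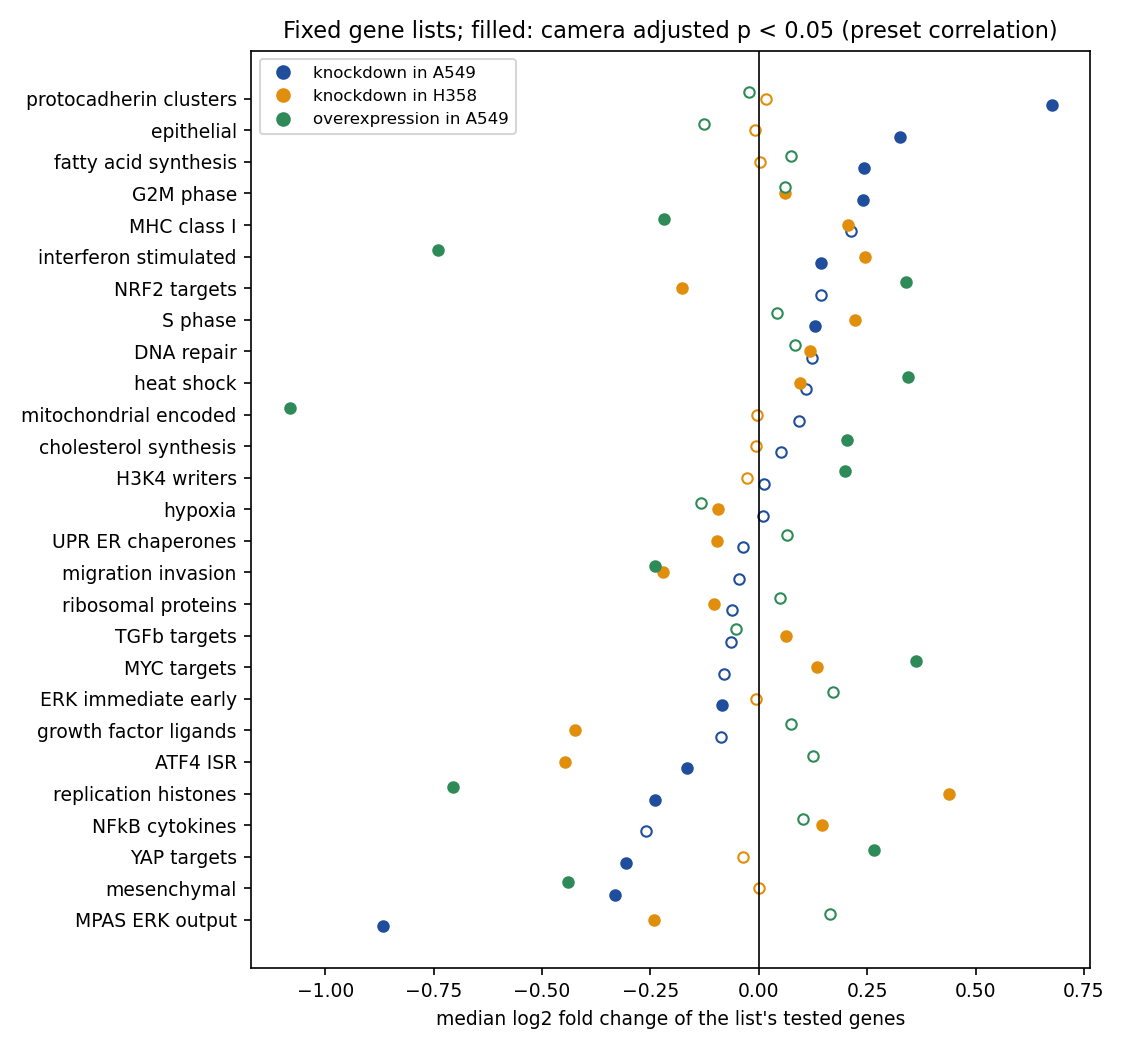
Median log2 fold change of fixed gene lists called in at least 1 of the 3 comparisons (blue, knockdown in A549; orange, knockdown in H358; green, overexpression in A549), filled where the camera adjusted p with a preset correlation is under 0.05. The MAPK activity score lies at -0.87 after knockdown in A549 and the mitochondrial genes at -1.08 with overexpression.

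Genes that follow the RAD21 level would move in opposite directions with knockdown and overexpression. In A549, 1574 genes were called in both comparisons and 1038 of them, 65.9%, moved in opposite directions. Of these, 569 rose with knockdown and fell with overexpression, where independent lists would share 348.4, and 469 fell and then rose, where 278.9 would be shared (odds ratio 0.267, Fisher's exact p = 8.3e-37, across genes, which are not independent replicates). Over all 15306 genes tested in both, Pearson's r of the log2 fold changes was -0.151 and Spearman's rho -0.189. After correction for GC content and length r was -0.0885. Of 667 genes called in both knockdowns, 406 moved the same way and 261 the opposite way (odds ratio 2.65, Fisher's exact p = 1.37e-09). Among them were 202 higher in both against 102.9 for independent lists and 204 lower in both against 95.13. Over all genes tested the fold changes of the lines showed no relation in size, with r at 0.0214 and rho at -0.00246. Without A549 shRAD21 replicate 3, r was -0.000315. The 2 knockdowns followed GC content in opposite directions (rho -0.414 in A549 and 0.26 in H358), which may hide a shared response. Of the 558 genes called with knockdown in H358 and with overexpression in A549, 59.0% moved the same way, with r at 0.0295 and rho at 0.122 over all genes, and 0.155 and 0.214 over genes of at least 4 CPM. Of the 27 that changed at least 2-fold in both, 18 moved the opposite way. Knockdown in H358 and overexpression followed GC content in the same direction (rho 0.26 and 0.37), so their agreement may in part follow that trend.

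**Figure D5:**
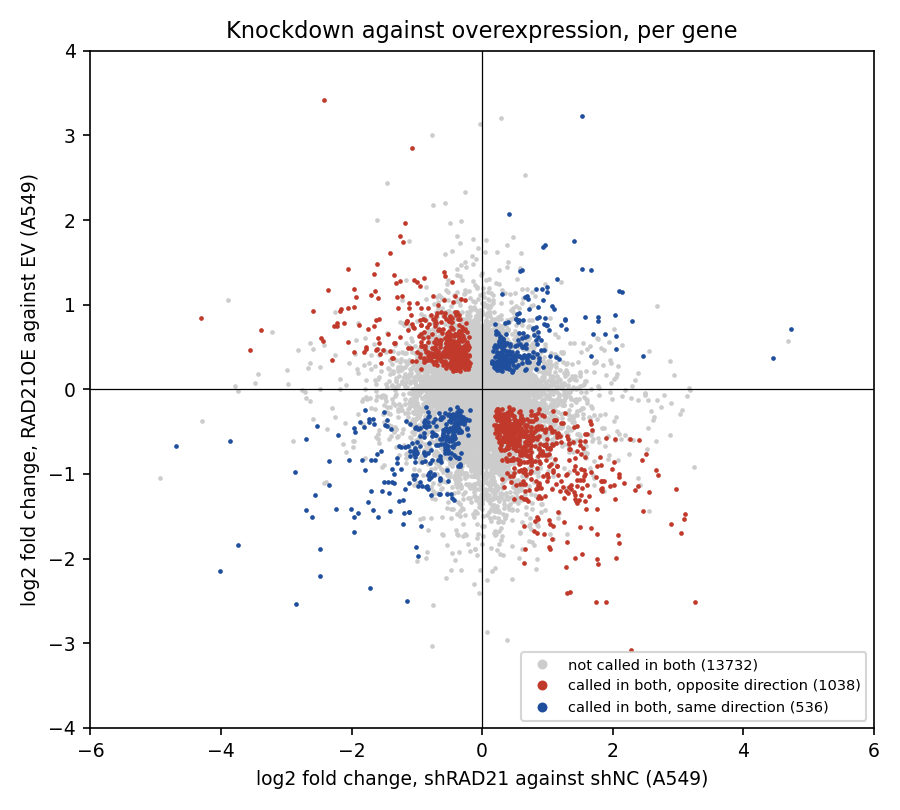
Log2 fold changes of 15306 genes after knockdown (x axis) and overexpression (y axis) of RAD21 in A549, 1 point per gene, with red for genes called in both comparisons in opposite directions and blue for the same direction; 1 gene lies outside the axes. The red points number 1038 of the 1574 called in both.

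A small set of genes followed RAD21 in all 3 comparisons: 36 were lower in both knockdowns and higher with overexpression, where independent lists would share 14.6, and 49 were higher in both knockdowns and lower with overexpression, where 15 would be shared. The other sign patterns also exceeded independence, with 18 to 43 genes each, 1.38 to 2.77 times the number expected. The 36 genes lay at 2.47 times and the 49 at 3.27 times. The excess of the 36 thus lies within the range of patterns that do not follow RAD21. Among the first set, AREG had log2 fold changes of -0.68 with knockdown in A549, -0.996 in H358 and 0.70 with overexpression. The kinesin gene KIF21B had -0.58, -0.51 and 1.39, GDF15, a secreted stress cytokine, had -1.62, -0.69 and 0.46, SOCS3, an inhibitor of cytokine signalling, -1.52, -0.53 and 0.46, and the cytokine gene LIF -0.77, -0.45 and 0.49. Among the second set, MX1 had 1.76, 1.30 and -2.00, PRR15L 3.10, 1.67 and -1.53, TRIM29, of keratinizing epithelia, 1.44, 2.30 and -1.32, and PHEX, a peptidase gene of bone mineralization, 2.09, 0.79 and -1.03. DOCK2 (2.06 in A549, -2.00 with overexpression) and TNS1, which links integrins to actin (1.84 and -1.17), were at 0 counts in all H358 shNC libraries, and there rose at least 3.17-fold and 5.99-fold against a floor of 3 counts over the group. With single libraries left out, the H358 calls of LIF (adjusted p of up to 0.17 without shRAD21 replicate 3), PHEX (0.144 without shRAD21 replicate 3), SOCS3 (0.0793 without shRAD21 replicate 3), DOCK2 (0.0957 without shRAD21 replicate 2) and KIF21B (0.0501 without shNC replicate 1) were lost, as were the overexpression calls of SOCS3 (0.0527 without EV replicate 1) and PHEX (0.0744 without EV replicate 1). After correction for GC content and length the 2 sets held 123 and 142 genes, and 0 and 6 when edgeR's calls also needed a change of at least 2-fold.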

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

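Several tests were chosen only after the result was seen, as was the correction for GC content and length. These tests concerned a weaker knockdown or overexpression, and opposite GC trends and the replicates numbered 3 behind the opposite fold changes. They also concerned a fall of all mitochondrial transcripts alike and weaker selection of polyadenylated RNA.

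The effect of knockdown differed between the lines, by the test of the difference itself, for 77 of 141 named genes. Over all genes tested the share was 17.6%. The named genes were chosen largely by their changes in these data, some by this difference, so their higher share carries no weight. With the preset correlation the effect of knockdown also differed for 15 lists, 14 of them given here, and with an estimated correlation for 0. RAD21 was depleted less in H358, so the line and the strength of depletion cannot be told apart. Values are the log2 fold change in H358 minus that in A549. Genes that fell more in A549 were ETV4 1.69, ETV5 1.08, SPRY4 1.06, PHLDA1 0.88, DUSP6 0.83, SPRY2 0.57, DUSP4 0.39, GDF15 0.93, SOCS3 0.99, RAD21 itself 0.57, CLDN1 1.71, JUP 1.15, LOXL2 0.81, MYOF 0.44, EFEMP1 3.41, IGSF10 3.40, UNC13A 3.13, SYT1 2.19, PRDM1 2.36, PCDHAC1 1.48, ISG20 0.88, BOD1 0.47 and KDM5C 0.38. Above 0 also lay SPARC 2.71, FBXO2 2.79, IFI27 2.19, IFI6 1.39, L1CAM 1.72, KCNH2 1.49, REC8 1.22, UNG 0.76, ATF5 0.76, RIOX1 0.68, CDCA5 0.63, SRM 0.41 and SETD1A 0.40.

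Below 0 lay genes that rose in A549: CEACAM6 -3.69, CEACAM5 -4.61, LCN2 -4.84, GDA -3.11, LSR -2.44, ITGB6 -2.50, CDH2 -1.31, EPHA4 -1.22, KRT18 -0.68, PCDHGC3 -1.22, PCDHA4 -0.93, DTX3L -0.90, LGALS3BP -0.59, PHEX -1.31 and F3 -0.54. The same sign held for KMT2C -0.70, PDS5B -0.65, SMC4 -0.66, TOP2A -0.34, CTCF -0.32 and KDM1A -0.30, and for genes that fell in H358 or rose more in A549: SPP1 -3.09, ABCA4 -3.21, DTX4 -2.33, TMC1 -1.96, SLC7A11 -1.32, EREG -0.74, ABCC3 -0.62, ITGA6 -0.55 and AREG -0.32.

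Fitted differences of genes at or near 0 counts in a group are no bounds: ANKRD1 6.71 and TNS1 3.63, at 0 counts in H358 shNC, rose there at least 5.29-fold and 5.99-fold. COL11A1 6.56 and COL27A1 4.68, also at 0 there, lay at least 2.12-fold and 3.53-fold higher in H358 shRAD21 but did not pass the test in H358 itself (adjusted p = 0.0881 and 0.0714). LY6D 5.13 and SLIT2 4.99 were at 0 in A549 shRAD21, at least 3.43-fold and 4.8-fold lower. JPH1 -4.79 and HSH2D -4.31 rose at least 3.24-fold and 2.27-fold in A549 from 0, and NLRP2 -4.58 fell at least 2.52-fold in H358 to 0. MCTP2 -5.05 had 38 counts against 1 in A549 (ratio 36.9, 95% counting interval 6.24 to 1500) and PELI2 -4.16 had 1 against 10 in H358 (ratio 0.106, 0.00244 to 0.744).

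Without single libraries the calls of several of these differences were lost, with an adjusted p of up to 0.127 for COL27A1 (without H358 shRAD21 replicate 3), 0.0808 for NLRP2 and 0.18 for PELI2 (both without H358 shNC replicate 2), 0.0739 for HSH2D, 0.068 for BOD1, 0.0848 for KDM5C and 0.076 for ATF5 (all without A549 shNC replicate 1) and 0.154 for F3 (without A549 shRAD21 replicate 1). After correction for GC content and length CTCF had 0.276 and SETD1A 0.317, and with no filter on low counts KDM1A had 0.113.

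The median difference of the lists was 0.70 for the MAPK activity score, 0.29 for mesenchymal genes, 0.28 for YAP targets, 0.42 for NF-kB targets, 0.38 for TGF-beta targets, 0.21 for MYC targets and 0.66 for histones. It was -0.20 for genes of the G2 and M phases, -0.37 for epithelial genes, -0.24 for fatty acid synthesis, -0.17 for ATF4 targets, -0.25 for NRF2 targets, -0.68 for protocadherins and -0.14 for housekeeping genes. Many of the protocadherins were at low levels in A549. With an estimated correlation camera kept 0 of the 15. With genes at 0 in a group set to their bound the medians were 0.45 for mesenchymal genes, 0.52 for NF-kB targets, 0.33 for TGF-beta targets, 0.33 for YAP targets and -0.32 for NRF2 targets.

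Of 100 splits of the libraries within the lines, drawn from 200, the real one called 3325 genes and no other as many. The other splits mix shRAD21 and shNC libraries within a line or exchange them in 1 line. None of them tests equal effects in both lines, so they cannot exclude chance for a difference between the lines. The highest other, 3231, was the split that exchanges shRAD21 and shNC in 1 line, and the next 1438. For the 3 comparisons 1 of 10 splits, the real one, gave as many genes, and 10 splits cannot give a share under 0.05. The real values were 4780, 1591 and 4297 genes in A549, H358 and with overexpression, and the highest others 0, 0 and 0 by edgeR, with up to 4419, 548 and 292 genes at an unadjusted p under 0.05. For the lists 1 of 10 splits each gave as many, with 13, 18 and 13 lists called against at most 9, 9 and 11.

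Replicate 3 of A549 shRAD21 and replicate 3 of RAD21OE stand apart from their groups. After a correction for trends on GC content and exon length the larger median absolute log2 difference to the other replicates fell from 0.282 to 0.134 and from 0.246 to 0.126, still above 0.0993, the highest among other pairs, so such a trend may account for part of the distance and what causes the rest cannot be told apart. For shRAD21 replicate 3 a weaker knockdown is argued against by RAD21, lowest in this library (101.1 CPM, against 128.9 CPM in the next). The slope of its deviation on the fold change of the other replicates was below 0, however, as weaker changes in other genes would give. Noise and GC trends of those replicates enter both sides and also push the slope down. Weaker changes in other genes therefore stay open. That slope was -0.453 before and -0.199 after the correction. For RAD21OE replicate 3 that slope was 0.0558 (95% interval 0.0337 to 0.0747) before and -0.0395 after the correction, where a weaker overexpression would give -0.0718; it stays open. No biological explanation was tested, since the labels give none.

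Fold changes with knockdown and with overexpression in A549 ran in opposite directions, with r at -0.151 across genes. GC trends running in opposite directions are argued against as the whole cause by r at -0.0885 (95% interval -0.117 to -0.0622) after the correction, with 1478 of 2592 genes called in both opposite, and the replicates numbered 3 by r at -0.13 (-0.154 to -0.101) without both, with 2105 of 3382 opposite. However, 27 of 100 combinations of splits gave an r as far from 0 and the highest other reached 0.324, so chance cannot be excluded. A response to the RAD21 level may account for part of the pattern and stays open as a hypothesis. For the shared response of the lines 31 of 100 combinations gave an r as far from 0 as the real 0.0214 (highest other 0.0534), so chance cannot be excluded there either.

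With overexpression the mitochondrial mRNAs fell and the rRNAs rose. Mitochondrial genes together took a smaller share of the counts in the RAD21OE libraries. A fall of all mitochondrial transcripts alike is argued against by the lower of the 2 rRNA changes, 0.55. It lies above 0 by more than 2 standard errors. A GC trend is argued against by the median of the 13 mRNAs, -0.99 after the correction. Weaker selection of polyadenylated RNA would raise the replication-dependent histones, which lack a tail. They had a median of -0.71, with 8 of 14 lower and none higher. Histone mRNAs may also change on their own account, and whether mRNA was selected is not given, so they cannot decide. The call of the histone list was lost with an estimated correlation (camera adjusted p = 0.266). RN7SL2, also without a tail, was at 0.39 (SE 0.35, adjusted p = 0.43), too uncertain to decide. A change in mitochondrial transcription or RNA decay may be behind it, a hypothesis that came from these data and was not tested. Depletion of rRNA by a protocol that differs between the groups was not tested either.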

How the results depend on the processing

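The correction for GC content and length, robust dispersion estimates, library totals alone and the settings without the replicates numbered 3 in the comparison of fold changes were chosen only after the result was seen.

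Of 9694 values of genes that meet the rule for naming under the alternatives, 8911 kept their direction and their side of the threshold, 770 lost the threshold, 8 gained it and 5 changed sign. All alternatives kept 142 of 174 called values in the knockdown in A549, 73 of 118 in H358, 109 of 157 with overexpression and 113 of 142 for the difference. No setting moved the median of all genes by more than 0.0783 on the log2 scale. The values that changed sign did not pass the test: CCND1 in H358, at 0.00085 without H358 shNC replicate 2 and 0.00602 without H358 shRAD21 replicate 1 (range with 1 library left out -0.053 to 0.00602), and DUSP4 with overexpression. DUSP4 had -0.0177 with at least 10 CPM, -0.0572 after the correction and -0.0255 without RAD21OE replicate 3 (range with 1 library left out -0.0255 to 0.0541). The cause was not tested.

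In A549, 1649 genes were higher with only the 6 libraries of the line. In H358 that setting gave 2186 higher and 2287 lower, the replicate block 455 and 583, and the correction 1713 and 1700; the cause was not tested in either line. With 1 library left out the higher and lower genes numbered 2003 to 4537 and 1410 to 3893 in A549, both highest without shRAD21 replicate 3, 347 to 386 and 408 to 496 in H358, where all 6 libraries move the count, 1112 to 2848 and 1065 to 2688 with overexpression, and 932 to 3507 and 1246 to 3841 for the difference. Deviations of treated and control libraries with the same replicate number correlated at -0.118, -0.0814 and -0.226 in A549. The values were 0.189, 0.000509 and 0.132 in H358, and -0.0345, 0.187 and 0.0786 with overexpression. For different numbers they lay between -0.123 and 0.196 in A549, -0.181 and 0.0703 in H358, and -0.141 and 0.0636 with overexpression. The replicate numbers thus showed no pairing in A549, and in H358 and with overexpression pairing stays open.

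For the lists, an estimated correlation left 0 higher and 1 lower in A549, 1 and 4 in H358 and 0 and 0 with overexpression by camera, a stricter test by construction. Fry called 13 higher and 13 lower in A549 and 10 higher with overexpression, and the correction 4 lower in A549 and 10 higher with overexpression. With 1 library left out the called lists numbered 6 to 8 higher and 5 to 8 lower in A549, 9 to 10 and 7 to 8 in H358, and 6 to 9 and 5 to 7 with overexpression.

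The correlation of the 2 knockdowns, near 0 throughout, was -0.0028 for genes of at least 4 CPM and -0.000315 without A549 shRAD21 replicate 3. That of knockdown and overexpression in A549 was -0.201 for genes of at least 4 CPM, -0.0885 after the correction, and between -0.193 and -0.114 with replicates numbered 3 left out. The genes following RAD21 in all 3 comparisons numbered 123 and 142 after the correction and 0 and 6 with a change of at least 2-fold, where fewer genes qualify.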

Other observations

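The test of the order along the mitochondrial genome was chosen only after the result was seen.

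Several further lists were called. After knockdown in A549, of 19 genes of fatty acid synthesis and desaturation 9 rose and 2 fell (camera adjusted p = 0.00731; adjusted p = 0.0875 with an estimated correlation), with the desaturase gene FADS1 at 0.73, the elongase gene ELOVL6 at 1.01 and the desaturase gene SCD at -0.48. With overexpression, of 25 genes of cholesterol synthesis 10 rose and 1 fell (camera adjusted p = 0.00626; adjusted p = 0.281 with an estimated correlation). Of 16 heat shock genes 10 rose and none fell (camera adjusted p = 0.00029; adjusted p = 0.395 with an estimated correlation), with HSPA8 at 0.58, and of 14 histone genes 8 fell and none rose (camera adjusted p = 0.000107; adjusted p = 0.266 with an estimated correlation), with HIST1H2BC at -1.72. In H358, of 49 ribosomal protein genes 6 fell and none rose (camera adjusted p = 7.39e-06; adjusted p = 0.547 with an estimated correlation), and of 15 histone genes 4 rose and none fell (camera adjusted p = 2.39e-05; adjusted p = 0.124 with an estimated correlation), the opposite direction to overexpression. Adjusted over the list alone, the genes higher and lower numbered 10 and 2 for fatty acid synthesis, 11 and 1 for cholesterol synthesis, 10 and 0 for heat shock and 0 and 8 for histones, and in H358 0 and 6 for ribosomal proteins and 5 and 0 for histones.

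Called genes next to each other on a chromosome moved the same way more often than in shuffles of the directions within 20 classes of GC content. The share was 71% of 1155 pairs after knockdown in A549 (95th percentile of shuffles 61.6%), 74.5% of 145 pairs in H358 (60.7%) and 68.2% of 1073 pairs with overexpression (59.1%), each with a permutation p = 1e-04, the smallest that 10000 shuffles can give. After correction for GC content and length the shares were 63.7%, 62.9% and 58.3%. Shared regulation of neighbours may contribute, which was not tested. Overlapping genes counted without strand could do so too.

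Along the mitochondrial heavy strand the log2 fold changes with overexpression fell with distance from the start of MT-RNR1 (Spearman's rho -0.692 over 14 genes, permutation p = 0.0078). Over the 12 mRNAs alone rho was -0.51 (permutation p = 0.094), so an order among the mRNAs may or may not be there, and the relation may rest on the 2 rRNAs.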
